A study of Homo sapiens with 6 samples.

How the data were processed

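Total RNA from 92.1 uveal melanoma cells was extracted with Trizol and made into libraries with a NEBNext Ultra kit, per the labels' protocols. Reads were aligned with STAR to hg38 and counted per gene with HTSeq 0.6.0, and DESeq2 was used, per the submitters' processing notes. The annotation, the strand setting and the way messenger RNA was selected are not given in the sources used here. The deposited values are whole-number counts per gene, not normalised by the authors, as the values themselves show. There were 2 deposited tables with the same 19932 gene symbols, one holding replicates 2 and 3 of both groups and the other replicate 1 of both. No row lacked a gene name, and 19907 of the genes are protein coding in GENCODE release 29. All symbols matched that release, which supplied gene identifiers, GRCh38 coordinates, exonic length and GC content.

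The 6 libraries were grouped from the treatment in the labels, 3 with the vector and 3 with METTL14. Total counts ran from 12086019 to 19675618, with mitochondrial transcripts at 12.5% to 13.3%. Pairs of libraries within a group gave a mean chi-square per gene of 1.52 to 3.04, and pairs across groups gave 11.4 to 19.5. Within a group, pairs in the same deposited table gave 1.524 and 1.56, and pairs across the 2 tables gave 2.755 to 3.041. All lie above sampling noise, so no library was treated as a repeat of another. The values do not show that the replicates came from separate cultures. The first principal component of log2 CPM (prior count 2) held 55.7% of the variance and separated the groups.

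Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group with a minimum count of 10, glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the 12177 genes kept and a threshold of 0.05. The biological coefficient of variation was 3.65%. CPM values are TMM-scaled means with the SD over 3 libraries. Before the data were examined, 53 gene lists were fixed, of which 50 had at least 3 tested members. These were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Symbols in the lists that differ from those in the tables were matched through current names where possible.

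Genes named in the text follow a rule fixed at the same time. METTL14 and FAT4 are always given. Of the other genes with FDR under 0.05, a mean CPM of 5 or more and groups that do not overlap, the 12 largest rises and 12 largest falls are given. For each list described, up to 4 members are given: the 2 with the smallest p among those that rose and the 2 among those that fell. All m6A writer partners are given. Some list members that the rule names are not reported here.

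On counts simulated from these libraries for the METTL14 comparison over 12004 genes, 44% of genes changed by a log2 of 0.3 were recovered, 89.8% at 0.6, 93.8% at 1 and 100% at 2, with 4.73% of calls false. With no change simulated, 0 genes were called. The simulation held 50, 49, 48 and 50 changed genes at log2 0.3, 0.6, 1 and 2, far fewer than the 4647 called in the data. Its adjusted threshold was therefore stricter, and the recovered shares do not carry over to the data.

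Alternatives were other scalings (DESeq2 size factors, upper quartile), other filters on low counts, the replicate number as a block, DESeq2 1.42.0, limma-voom, leaving out mitochondrial genes or each library in turn, robust fitting and a test against a 1.2-fold change. Offsets for GC content and exonic length, the table with replicates 2 and 3 alone, the table as a covariate and scaling to total count were added after the data were seen.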

Results

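Messenger RNA was counted per gene in 6 RNA-seq libraries from 92.1, an established human uveal melanoma line that carries a GNAQ mutation. The libraries fell into 2 groups of 3: cells given an empty vector and cells given a lentivirus to overexpress METTL14, all taken at 72 hours. METTL14 is the RNA-binding partner of METTL3 in the nuclear complex that writes N6-methyladenosine (m6A) into messenger RNA. Total counts were 13702934, 12086019 and 19675547 in the vector libraries and 15846789, 12567688 and 19675618 in the METTL14 libraries. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Genes are named by the symbols in the deposited tables, and coordinates are those of GENCODE release 29 on GRCh38.

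The comparison asked which transcripts differ between cells that overexpress METTL14 and cells with the vector. METTL14 itself rose 5.09-fold, from 21.7 ± 1.56 to 111 ± 6.34 TMM-scaled CPM (SD, n = 3 per group). Its log2 fold change was 2.35 with a standard error of 0.06 (edgeR quasi-likelihood, adjusted p = 5.2e-21). The gene (ENSG00000145388.14) lies on chromosome 4 at 118685368 to 118715433, plus strand, and the counts do not separate transgene reads from those of the cell's own gene. FAT4, a giant atypical cadherin that acts upstream of the Hippo pathway (ENSG00000196159.11, chromosome 4, 125316399 to 125492932, plus strand), rose 3.83-fold, from 2.85 ± 0.77 to 10.5 ± 1.37 CPM (SD, n = 3). Its log2 fold change was 1.94 with a standard error of 0.17 (edgeR, adjusted p = 4.3e-10). FAT4 was included because it is remembered as a gene this study followed up, so its rise is not independent evidence. For both genes every METTL14 library lay above every vector library, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 allows. In the deposited table that holds replicate 1 alone, where no test is possible, the log2 differences were 2.39 for METTL14 and 2.00 for FAT4.

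**Figure D1:**
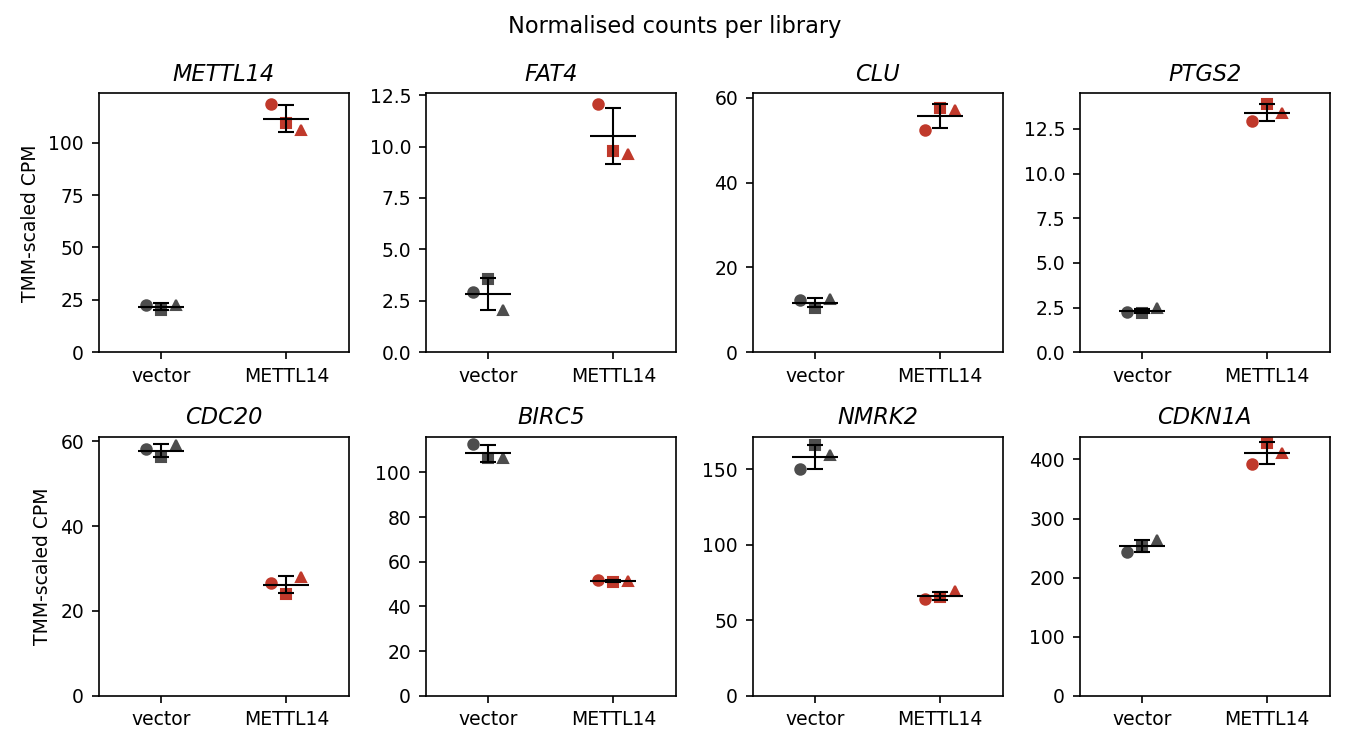
Normalised counts of 8 genes in each of the 6 libraries, as TMM-scaled CPM on axes that start at 0, with the vector libraries in grey and the METTL14 libraries in red; marker shapes give the replicate number, the dash is the group mean and the bar 1 SD (n = 3). METTL14 lies between 19.9 and 22.7 CPM with the vector and between 106 and 119 CPM with the lentivirus, and the other genes shown also have groups that do not overlap.

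Cells that overexpressed METTL14 had lower levels of transcripts for DNA replication and mitosis, and higher levels of CDKN1A, a p53 target that inhibits the cell cycle, and of the antioxidant gene NQO1. Of the listed genes, 38 of 40 for replication and 34 of 38 for mitosis fell. Of 12177 genes tested, 4647 changed (edgeR quasi-likelihood, FDR 0.05), 2194 higher and 2453 lower. Most of the changes were small: the median fold of the called genes was 1.22, and 86.6% of them changed by less than 1.5-fold. A log2 change of 1 or more was reached by 116 genes that rose and 31 that fell. The groups did not overlap in 5715 genes, or 46.9%, where chance gives 10%. Scaled to total count in place of TMM, 3500 genes were higher and 1451 lower, and the median of all genes shifted from 0.01 to 0.09, so the balance of higher and lower genes depends on the scaling. With replicates 2 and 3 alone, which share a deposited table, 4528 genes changed, and of 4516 of them that could be followed 4336 had the same direction in replicate 1.

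Among genes with a mean CPM of 5 or more, EDIL3, an integrin-binding matrix protein, rose from 2.22 ± 0.89 to 14.6 ± 1.45 CPM (log2 2.66), and CLU, the secreted chaperone clusterin, from 11.7 ± 1.12 to 55.7 ± 2.91 CPM (log2 2.24; SD, n = 3 per group). PTGS2, the inducible cyclooxygenase, rose by a log2 fold change of 2.52. ANXA1, a phospholipid-binding protein of inflammation control, rose by 1.80, and SLC7A11, the cystine importer, by 1.69. GJD2, the gap junction protein connexin 36, rose by 1.84, whereas another gap junction gene, GJB1 (connexin 32), had a log2 fold change of -1.08. LAMB3, a laminin chain, rose by 1.35, and ECM1, an extracellular matrix protein, by 1.21. With METTL14 and FAT4 set aside, the remaining leading rises were ATXN1 at 1.40, the transporter gene SLCO5A1 at 1.27, the elongation factor gene EEF1A2 at 1.18 and the histone gene HIST1H2BD at 1.47. HIST1H2BD and EEF1A2 have near-identical relatives, so the share of their reads that is their own is uncertain. The adjusted p-values of these 12 rises lay between 2.0e-18 for CLU and 6.9e-07 for EEF1A2 (edgeR).

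Of the 12 largest falls among genes with a mean CPM of 5 or more, 5 were members of the list of mitosis genes. NMRK2, a nicotinamide riboside kinase, had the largest of them, from 158 ± 7.91 to 66.1 ± 2.75 CPM (log2 -1.26). The mitotic kinase AURKB had a log2 fold change of -1.16, the separase gene ESPL1 -1.14, the anaphase activator CDC20 -1.14 and the survivin gene BIRC5 -1.08. GTSE1, which acts in G2 and mitosis, had -1.06, the centromere chaperone HJURP -1.04 and the phosphatase gene CDC25C -1.02. FOXN4, a forkhead transcription factor, had -1.11, PSMC3IP, a recombination cofactor, -1.10, and ERFE, the hormone erythroferrone, -1.04. Exons of PSMC3IP overlap those of MLX on the other strand over 29.9% of their length, and the kit named in the labels is not said to keep strand, so its reads are uncertain. The same limit holds for IFITM3, CRYAB, RBM15B, NQO1, KRT18 and FOXM1, named below, with overlaps from 15.9% for FOXM1 to 21.3% for IFITM3. The adjusted p-values of these 12 falls lay between 1.5e-17 for NMRK2 and 1.1e-05 for ERFE (edgeR).

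**Figure D2:**
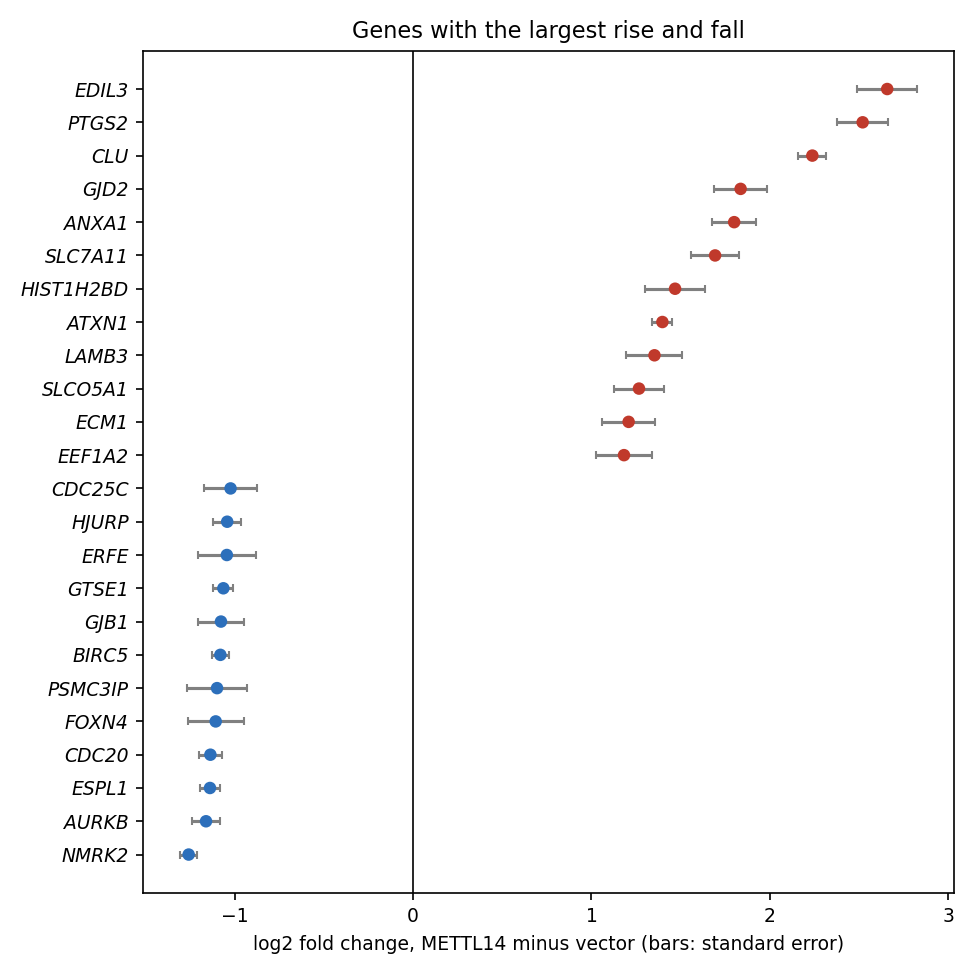
Log2 fold change, METTL14 minus vector, of the 12 genes with the largest rise (red) and the 12 with the largest fall (blue) by the rule fixed in advance, METTL14 and FAT4 set aside. Bars are standard errors from edgeR (n = 3 per group). Rises extend from 1.18 for EEF1A2 to 2.66 for EDIL3 and falls from -1.02 for CDC25C to -1.26 for NMRK2.

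Of 50 gene lists tested, 12 stood apart from the other genes (camera with a preset correlation of 0.01, FDR 0.05), 5 higher and 7 lower. With an estimated correlation, 2 of them were still called, and both were cell-cycle lists. The estimate was below the preset for the p53 (0.0091), YAP and TAZ (-0.038), melanocyte (-0.013), unfolded protein response (-0.0032) and PI3K (-0.023) lists. A larger correlation between genes is therefore not why those calls were lost. Of 40 genes of DNA replication and the G1/S transition, 38 fell, 0 rose and 2 did not pass, with a median log2 fold change of -0.63 (camera, adjusted p = 4.5e-22; adjusted p = 0.0079 with an estimated correlation). MCM7, a subunit of the replicative helicase, fell from 305 to 171 CPM (log2 -0.83), and TK1, thymidine kinase, from 139 to 71.1 CPM (log2 -0.97). Of 38 genes of mitosis and G2/M, 34 fell, 0 rose and 4 did not pass, with a median of -0.81 (camera, adjusted p = 1.2e-21; adjusted p = 0.0079 with an estimated correlation). FOXM1, the transcription factor that drives mitotic genes, had a log2 fold change of -0.99. Adjusted over the list alone, 38 replication genes and 35 mitotic genes fell. With total count the medians were -0.55 and -0.73, with 38 and 33 genes lower.

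Among 25 p53 targets, 14 rose, 2 fell and 9 did not pass, with a median of 0.23 (camera, adjusted p = 0.00030). This call was lost, at adjusted p = 0.175, with an estimated correlation, and with total count 18 rose and 0 fell (median 0.31). CDKN1A, which encodes p21, rose from 253 to 411 CPM (log2 0.70), and the kinase gene PLK2 rose by 0.83. POLH, a translesion polymerase, and AEN, a nuclease, fell, with log2 fold changes of -0.18 and -0.14. Neither call is firm. That of POLH was lost without vector replicate 1, with replicates 2 and 3 alone and with total count (edgeR, adjusted p = 0.0817, 0.0823 and 0.144). That of AEN was lost without vector replicate 1, vector replicate 3 or METTL14 replicate 3 (edgeR, adjusted p = 0.0503, 0.155 and 0.267). The AEN call was also lost with upper-quartile scaling, GC and length offsets and total count (edgeR, adjusted p = 0.102, 0.163 and 0.373) and in DESeq2 (adjusted p = 0.0627). All 6 tested members of the list of replication-dependent histones rose, with a median of 0.86 (camera, adjusted p = 0.00019; adjusted p = 0.188 with an estimated correlation). HIST1H2BK rose by 0.56. Histone transcripts mostly lack a poly(A) tail and belong to families that share sequence, so these values are uncertain.

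Of 18 targets of the antioxidant regulator NRF2, 9 rose, 3 fell and 6 did not pass, with a median of 0.12 (camera, adjusted p = 0.029; adjusted p = 0.367 with an estimated correlation). Without 1 library the median of the NRF2 targets ran from 0.095 (without vector replicate 3) to 0.21 (without METTL14 replicate 1 or 3), and with total count it was 0.20, with 11 higher and 0 lower. NQO1, a quinone reductase, rose from 851 to 1201 CPM (log2 0.50), and TXNRD1, thioredoxin reductase, rose by 0.48, while the pentose phosphate enzymes TKT and TALDO1 each had -0.14. With total count neither TKT nor TALDO1 passed (edgeR, adjusted p = 0.110 and 0.214), and after offsets for GC content and length TALDO1 had -0.0065 (adjusted p = 0.880). Of 20 targets of the Hippo effectors YAP and TAZ, 8 rose, 1 fell and 11 did not pass, with a median of 0.23 (camera, adjusted p = 0.0087; adjusted p = 0.204 with an estimated correlation). MYOF, a membrane repair protein, rose by 1.08 and GADD45A, which is also a p53 target, by 0.65, whereas AMOTL2, which restrains YAP, fell, with -0.17 (lost with total count, edgeR adjusted p = 0.0731). Of 22 genes of the PI3K, mTOR and FOXO pathways, 12 rose, 3 fell and 7 did not pass, with a median of 0.15 (camera, adjusted p = 0.035; adjusted p = 0.246 with an estimated correlation). IRS1, the insulin receptor adaptor, rose by 0.46 and the mTORC2 subunit gene RICTOR by 0.51, while the kinase genes AKT2 and AKT1 had -0.36 and -0.29. With total count the YAP and PI3K lists had 11 and 15 genes higher and 0 and 2 lower, with medians of 0.31 and 0.23.

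Of 45 cytosolic ribosomal protein genes, 32 fell, 1 rose and 12 did not pass, with a median of -0.15 (camera, adjusted p = 1.5e-07; adjusted p = 0.328 with an estimated correlation). RPL8 and RPS2 had -0.33 and -0.29, and RPS24 rose by 0.22; these genes have many pseudogene copies, so the values are uncertain. Of 33 nuclear genes of oxidative phosphorylation, 16 fell, 0 rose and 17 did not pass, with a median of -0.11 (camera, adjusted p = 0.00042; adjusted p = 0.204 with an estimated correlation). CYC1, cytochrome c1, had -0.38 and ATP5F1B, an ATP synthase subunit, -0.24. Of 20 genes of the unfolded protein response, 12 fell, 0 rose and 8 did not pass, with a median of -0.22 (camera, adjusted p = 1.4e-05; adjusted p = 0.10 with an estimated correlation). The endoplasmic reticulum chaperones CALR and HSPA5 had -0.66 and -0.44. Of 17 heat shock genes, 10 fell, 2 rose and 5 did not pass, with a median of -0.20 (camera, adjusted p = 0.029; adjusted p = 0.367 with an estimated correlation). The chaperone genes HSPA8 and STIP1 had -0.37 and -0.40, whereas CRYAB, a small heat shock protein, rose by 1.13 and DNAJB4 by 0.34. With total count these 4 lists still passed, but the medians were -0.068, -0.035, -0.14 and -0.13, with 20, 9, 10 and 8 genes lower and 1, 1, 2 and 4 higher. Beside these groups, GC content ran with the fold change across genes (Spearman's rho -0.31; genes are not independent replicates). After offsets for GC content and exonic length, the ribosomal protein, oxidative phosphorylation and PI3K lists no longer passed (camera, adjusted p = 0.135, 0.0687 and 0.606). Their medians were then -0.09, -0.11 and 0.11, so that of oxidative phosphorylation stayed about as large. The heat shock list was lost without METTL14 replicate 2 or 3 (adjusted p = 0.0536 and 0.0512), and the NRF2 list without vector replicate 3 or METTL14 replicate 2 (adjusted p = 0.0581 and 0.0891). The PI3K list was also lost without vector replicate 3 (adjusted p = 0.0581). With no filter on low counts the NRF2 and PI3K lists were lost (camera, adjusted p = 0.0650 and 0.0527).

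Of 22 melanocyte lineage genes, 11 fell, 2 rose and 9 did not pass, with a median of -0.19 (camera, adjusted p = 0.029; adjusted p = 0.245 with an estimated correlation). With total count 11 fell and 6 rose, with a median of -0.11. PMEL, the melanosome fibril protein, fell from 13947 to 9376 CPM (log2 -0.57), and TYRP1, a melanin synthesis enzyme, had -0.28, while ABCB5, a transporter, rose by 0.32 and the melanosome motor gene MYO5A by 0.14. After GC and length offsets MYO5A had 0.017 and did not pass (edgeR, adjusted p = 0.697). Lists of markers of other cells did not pass, that of the retinal pigment epithelium by little. Of the 4 fibroblast genes tested, COL1A1 alone rose (log2 0.49), and its call was lost without vector replicate 1, vector replicate 3 or METTL14 replicate 3 (edgeR, adjusted p = 0.0987, 0.0512 and 0.235). Its log2 fold change was then 0.38, 0.53 and 0.31. The COL1A1 call was also lost in DESeq2 (adjusted p = 0.0830). Of 3 carcinoma genes, 0 passed, with KRT18 at 0.11 and ESRP1 at 0.06, though KRT18 passed after the offsets (0.24, edgeR adjusted p = 0.0085). Of 5 embryonic kidney line genes, LIN28B rose (0.33) and CKB fell (-0.53). The call of LIN28B was lost without vector replicate 2, vector replicate 3, METTL14 replicate 1 or METTL14 replicate 3 (edgeR, adjusted p = 0.0756, 0.0755, 0.0851 and 0.0860). Its log2 fold change there was 0.29 to 0.33. The call was also lost with replicates 2 and 3 alone and after GC and length offsets (edgeR, adjusted p = 0.0613 and 0.119) and in DESeq2 (adjusted p = 0.0841). Of 6 retinal pigment epithelium genes, 4 fell, among them SERPINF1 with -0.37 and PMEL, which is also a melanocyte gene (camera, adjusted p = 0.052). That list passed without vector replicate 2 or METTL14 replicate 3 (adjusted p = 0.0286 and 0.0265), and with upper-quartile scaling, a mean count of 50 or more or total count (adjusted p = 0.0312, 0.0053 and 0.0152). Leukocyte and endothelial markers had 2 genes tested each, too few for a list test.

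**Figure D3:**
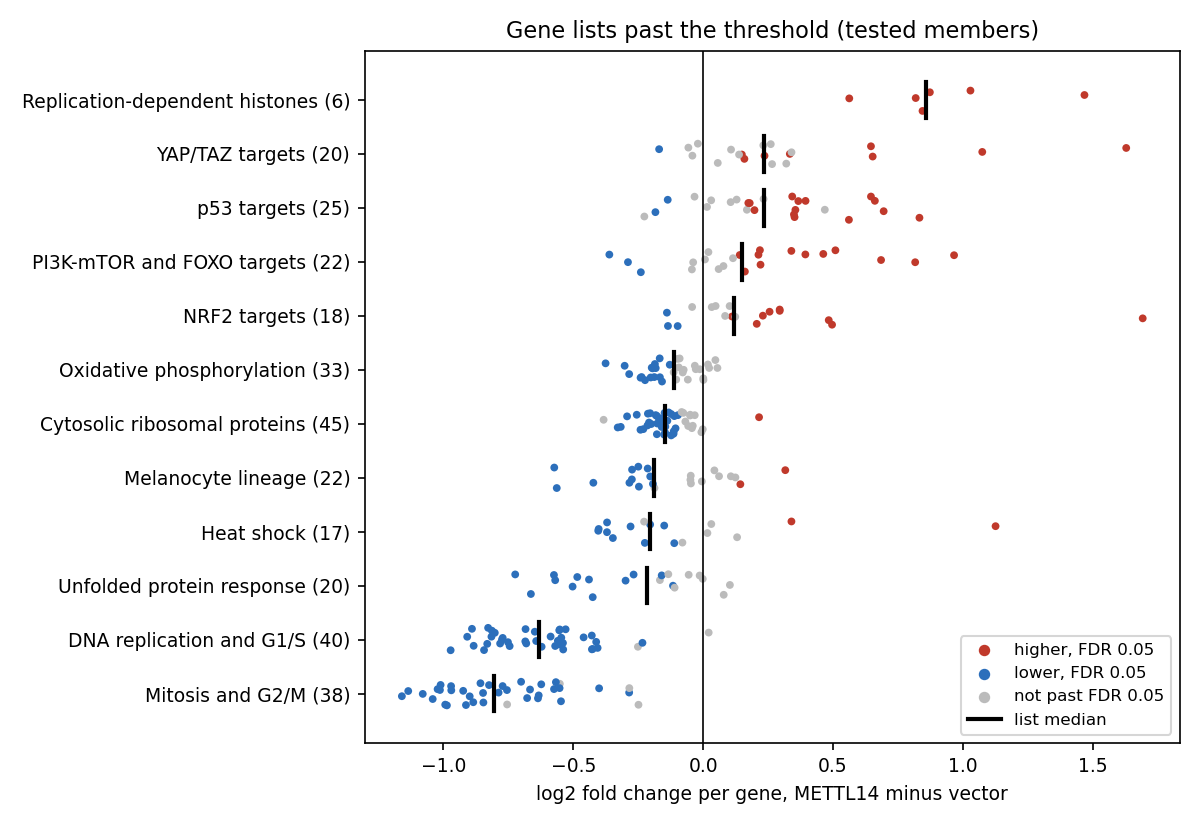
Log2 fold change of each tested member (points) of the 12 gene lists past the threshold, METTL14 minus vector, with members that rose in red, those that fell in blue and those not past FDR 0.05 in grey; black lines are list medians and numbers in brackets the tested members. Medians run from -0.81 for mitosis and G2/M to 0.86 for replication-dependent histones.

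Of the 7 partners of METTL14 in the writer complex, ZC3H13 rose by a log2 fold change of 0.43 (edgeR, adjusted p = 4.1e-08) and VIRMA by 0.20 (adjusted p = 0.0038), and 5 did not pass. Those were METTL3, the catalytic subunit, at -0.07, WTAP at 0.13, RBM15 at -0.09, RBM15B at -0.07 and CBLL1 at -0.10. The list's median was -0.07 and its mean 0.06, and camera gave adjusted p = 0.758, in the direction higher. After the GC and length offsets VIRMA did not pass (0.062) and CBLL1 did (-0.18), and with total count WTAP passed (0.21). Of 16 m6A erasers and readers, 6 rose, 5 fell and 5 did not pass (camera, adjusted p = 0.834), but with total count 8 rose and 1 fell (median 0.15). The readers EIF3A and FXR1 rose by 0.32 and 0.28, and HNRNPA2B1 and HNRNPC had -0.21 and -0.14, the latter lost with total count (edgeR, adjusted p = 0.139). Of the 8 atypical cadherins tested, 4 rose, 1 fell and 3 did not pass (camera, adjusted p = 0.413), with CELSR3 at 0.39 and CELSR2 at -0.29 beside FAT4.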

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

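The GC and length offsets, the table with replicates 2 and 3 alone, the table as a covariate and scaling to total count were chosen after the data were seen. METTL14 and FAT4 rose under every alternative run for them; without each library in turn their log2 fold changes ran from 2.30 to 2.39 and from 1.70 to 2.12. Leaving out a library gave 3571 (without vector replicate 3) to 4613 genes, 1610 to 2194 higher and 1961 to 2419 lower, 112 to 148 higher and 27 to 43 lower by log2 1 or more, all 24 genes named for the largest changes still past the threshold each time, and 11 to 15 lists. The count of called genes moved most against a 1.2-fold change (770 genes, 334 higher and 436 lower) and its split with total count (3500 higher, 1451 lower, 18 lower by log2 1 or more). No filter gave 50 genes lower by log2 1 or more, and a mean count of 50 or more gave 39 higher and 14 lower, as low-count genes entered or left the test. A smallest mean CPM of 1 kept 14 of the 24 named genes. An estimated correlation left 2 lists; fry, which does not compare a list with other genes, called 31. DESeq2 called 3699 genes, all with the same direction. After GC and length offsets 4702 genes passed, of which 3511 were among the 4647.

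For small effects the direction of the test or the sign turned. The median log2 fold change of the mitochondrial transcripts was 0.036 with upper-quartile scaling, 0.046 after offsets, 0.021 with replicates 2 and 3 alone and 0.083 with total count, where the test turned and the median kept its sign; it was -0.0090 without vector replicate 2, -0.0033 without vector replicate 3 and -0.018 without METTL14 replicate 1, where the sign turned and the test did not. That of collagens and matrix was -0.0015 with a mean count of 50 or more and 0.0062 after offsets. After offsets, the m6A writers had -0.0052 (test turned, same sign), erasers and readers -0.0047, ATF4 targets 0.021 and IFITM3 0.0057; without each library in turn, the m6A writers had -0.099 (without vector replicate 3, direction turned) to -0.017. With total count RBM15B had 0.0098, METTL3 0.0060 and the embryonic kidney list a median of 0.22 (test turned), and fry gave that list the other direction (median 0.14). None of these lists passed the threshold under those settings. IFITM3 was called lower in the main fit and did not pass after offsets (edgeR, adjusted p = 0.925). With total count the median of all genes was 0.087, against 0.00855 with TMM, so that scaling raised RBM15B and METTL3 along with genes as a whole. The cause of the other turns was not tested.

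The labels do not say that the replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.102, 0.037 and 0.046, and all 6 correlated best with their own number. That is a weak hint of pairing from the data and not the design. Replicate 1 of both groups shares a deposited table, so its 0.102 cannot be told apart from a difference between tables. In the other table, vector replicate 2 with METTL14 replicate 3 gave 0.0165, and vector replicate 3 with METTL14 replicate 2 gave 0.0111. With the number as a block 5664 genes passed, and the NF-kB list had a median of -0.024 with its direction turned. With the deposited table as a covariate 5479 genes passed. The planned use of a second deposited table was not run, since that table holds other replicates. At these depths 44% of simulated changes of log2 0.3 were recovered, so small changes may be missed. The simulation gave 169 calls against 4647 in the data, so its adjusted threshold was stricter. The share missed in the data is therefore not known.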

Other observations

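The melanocyte-marker test, the GC test within groups, the split of the ribosomal and respiratory lists, the checks on the neighbouring-gene run, and the settings with offsets, total count or the table as a covariate in the list results were chosen after results were seen; the other tests in this part were set before theirs.

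Several lists that did not stand apart as a whole held members that moved in opposite directions. Of all 12177 genes tested, 38.16% passed, 2194 higher and 2453 lower. Calls in both directions can therefore arise in a list without any tie to its pathway. Of 28 ATF4 targets, 7 rose and 10 fell (median -0.05, mean 0.08, camera adjusted p = 0.697): SLC7A11 rose by a log2 fold change of 1.69 and the mTORC1 inhibitor gene DDIT4 by 0.67, while the amino acid importer SLC7A5 and the serine pathway enzyme SHMT2 had -0.35 and -0.32. Exons of DDIT4 overlap those of DDIT4-AS1 on the other strand over 41.2% of their length, so its reads are uncertain. Of 22 MAPK outputs, 7 rose and 4 fell (camera, adjusted p = 0.758), with the feedback inhibitor SPRY1 at 1.13 and SPRY2 at 0.32 against the transcription factors ETV4 at -0.54 and ETV5 at -0.22. Of 32 hypoxia and glycolysis genes, 6 rose and 13 fell (camera, adjusted p = 0.156), with NDRG1 at 0.57 and BNIP3L at 0.38 against the glycolytic enzymes LDHA at -0.33 and GAPDH at -0.20. Of 14 angiogenesis factors, 1 rose, VEGFA at 0.29, and 6 fell (camera, adjusted p = 0.121; 0.0388 with total count), among them VEGFB at -0.42 and NRP2 at -0.33.

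Of 22 TGF-beta targets, 10 rose and 2 fell (camera, adjusted p = 0.054, and 0.367 with an estimated correlation): SKIL and GDF15 each had 0.70 and ID2 -0.28. That list lay near the threshold: it passed without vector replicate 2, vector replicate 3 or METTL14 replicate 1 (adjusted p = 0.0406, 0.0405 and 0.0336), with the deposited table as a covariate (0.0337), with the replicate block (0.0404) and after GC and length offsets (0.00083, median 0.23, 13 rose). Of 25 collagen and matrix genes, 7 rose and 5 fell (camera, adjusted p = 0.823), with COL12A1 at 2.47, from 0.22 to 1.27 CPM, and FBLN2 at 0.53, against FBLN1 at -0.52 and COL9A3 at -0.35. Of 23 cholesterol synthesis genes, 9 rose and 9 fell (camera, adjusted p = 0.519), with MSMO1 at 0.23 and SC5D at 0.34 against EBP at -0.40. Of 31 splicing factors, 8 rose and 11 fell (camera, adjusted p = 0.697), with SRSF11 at 0.39 and LUC7L3 at 0.42 against PTBP1 at -0.36; after GC and length offsets this list passed, lower (median -0.056, 5 rose, 15 fell, adjusted p = 0.0020). Of 25 interferon-stimulated genes, 4 rose and 4 fell (camera, adjusted p = 0.697), with STAT2 at 0.27 and OAS3 at -0.28, but 6 rose and 1 fell with total count (median 0.19) and 5 and 1 after offsets. Of 10 NF-kB and inflammatory genes, 1 rose, PTGS2 (median -0.02, mean 0.27, camera adjusted p = 0.880 in the direction higher). Of 13 mitochondrial transcripts, 3 rose and 4 fell (camera, adjusted p = 0.846), with MT-ND4 at 0.07 and MT-CO3 at -0.17; the counts depend on the setting, with 8 higher and 1 lower with total count, 8 and 2 after offsets and 0 and 2 in DESeq2. Total count moved other lists toward rises too: 8 higher and 5 lower for ATF4, 10 and 3 for MAPK, 11 and 4 for collagens and matrix, 9 and 5 for cholesterol, 12 and 9 for splicing factors.

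The fall of cell-cycle transcripts was tested against 3 technical explanations. After offsets for GC content and length the median of its 78 genes was -0.70 (bootstrap interval -0.76 to -0.65), with 75 genes lower. The scaling that moved it most, total count, left -0.61. The scalings tried shift genes nearly alike, with a median over all genes of 0.087 at most, so they could not have undone a fall of this size. They show only that the choice among them does not account for the fall. Cells of another type that do not cycle would lower melanocyte transcripts by as much, but these had a median of -0.19 (interval -0.25 to -0.0047), apart from the cell-cycle genes by 0.50 (permutation p = 1e-04, the smallest that the permutations drawn can give). This permutation and the bootstrap intervals in this part run over genes, which are not independent replicates. Culture density and the response to the virus itself remain open, since no value here separates them from METTL14.

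For the lower ribosomal protein and respiratory chain transcripts, the offsets do not settle a GC and length trend. The joint median over 78 genes moved from -0.14 to -0.104, with 44 genes lower against 48. As a point value the median lay just below -0.1, the bound set beforehand for the case of no such trend. Its bootstrap interval, -0.12 to -0.08, crossed that bound. Total count alone moved the median further, to -0.063, with 29 lower. The ribosomal protein median moved from -0.15 to -0.09 (interval -0.13 to -0.06, 29 of 45 genes still lower), while that of oxidative phosphorylation stayed at -0.11 (interval -0.13 to -0.09, 15 of 33 lower); both list calls ended (camera, adjusted p = 0.135 and 0.0687), and why the second ended was not tested. The correlation with exonic length was at most 0.101 in size within a group and 0.226 between groups. That with GC content reached 0.422 within a group, but between libraries of different deposited tables, each of which holds both groups; within a table it was -0.089 and -0.0693, against -0.266 and -0.285 between the groups in those replicates. Variation between libraries of a table was thus smaller than the trend between groups, for which a preparation difference between groups may be the source, and so may biology.

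Histone transcripts rose while replication genes fell, although histone genes are expressed in S phase. Of 15 histone genes tested, 9 rose and 0 fell, so 100% of the called ones rose, as more RNA without a poly(A) tail in the METTL14 libraries would give. Reads shared between near-identical genes could spread one change over a type, and 0 types had members called in both directions, which decides nothing with so few called genes per type. The tables hold no noncoding RNA from the list fixed for this purpose, so capture of RNA without a tail may explain the rise, and so may longer-lived or polyadenylated histone transcripts.

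Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave as many as 4647 genes. The highest of the others gave 0. Each of the others mixes vector and METTL14 libraries within a group, so the group difference widens its spread and keeps calls low. The splits therefore say nothing about chance, and 10 are also too few for a share under 0.05. The density of the m6A core motif GGACT in 3′ UTRs had a raw rank correlation of -0.0529 with the fold change across 11165 genes. No test was run on that raw value. Given UTR length, UTR GC, exonic length and transcript GC, the partial rank correlation was 0.00848 (permutation p = 0.372). No relation of GGACT beyond those properties was seen. For the broader DRACH motif the partial correlation, given the same properties, was 0.0427. No permutation test was run for DRACH, so a small relation with that motif stays open. The largest median of 50 neighbouring genes was 0.278, on chromosome 6 from 17600355 to 27865798, above the 0.26 set beforehand as the mark of a copy number difference and above the 0.212 reached in 100 shuffles. After GC and length offsets the largest median was 0.247, below that mark, and lay on nearly the same stretch, from 17759183 to 28130082. The bootstrap interval of the run without offsets was 0.12 to 0.33. That run holds 14 histone genes, and in it 23 genes passed higher and 3 lower. Without histone genes the largest median was 0.266, on chromosome 19. A copy number difference could be present, and clustered regulation stays open. The totals of vector replicate 3 and METTL14 replicate 3 differed by 71 counts, where the next closest pair of libraries differed by 481669.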
